A study of Arabidopsis thaliana with 7 samples.

How the data were processed

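RNA-seq was measured in 3 replicate samples of wild-type *Arabidopsis thaliana* Col-0, the reference accession, from seedlings kept for 14 days on MS medium at 22 °C with 16 h of light and 8 h of dark, per the labels' protocols. The series also holds 4 chromatin libraries (H3K4me1, H3K4me2, H3K4me3 and input), which were not analysed here. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separately grown plants, so every test below measures only the spread between these samples, which may be technical.

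The authors deposited raw counts per gene, 1 column per RNA library, for 33602 genes. Per the submitters' processing notes, the tools were cutadapt, HISAT2, Bowtie2 2.4.5, SAMtools 1.13, featureCounts and deepTools 3.5.1, and the build was TAIR10, with no role or order stated. The RNA was isolated with a plant kit and made into libraries with a stranded kit, per the labels' protocols. The annotation release, the strand setting, the handling of multi-mapping reads and the handling of read pairs by featureCounts are not given in the sources used here. Genes that share sequence with a near-identical copy, overlapping genes and antisense genes are therefore uncertain.

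Low counts in the deposited table were mostly even. Among genes with 1 to 19 counts, 86.2%, 85.6% and 84.5% of counts in replicates 1, 2 and 3 were even. Among genes with 1000 counts or more, 50.3%, 51.1% and 49.9% were even. Counts were not shown to be independent molecules, and intervals and floors given here cover counting error only.

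The library totals were 30946664, 18493022 and 20764970 counts in replicates 1, 2 and 3. A gene with 0 counts may still hold up to 3 counts of the total, which is 0.0969, 0.162 and 0.144 CPM in those libraries. All 279 chloroplast and mitochondrial genes of the table were listed at 0 in every library, so nothing is said of organelle transcription. Each column of the table belonged to 1 of the 3 RNA samples.

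From the counts, CPM (counts scaled to a fixed library total) were computed with edgeR 4.0.16 in R 4.3.3, with TMM scaling of the library totals (factors 0.989 to 1.01). A gene was called expressed at a mean of at least 1 CPM over the 3 libraries. Levels were planned as TPM, but no exon lengths of the authors' build were used here, so levels are CPM and depend on transcript length. For the same reason the planned comparison of level with gene length, exon number and GC content was not run, nor was the planned relation of transcription to H3K4 methylation. Gene symbols and gene types came from a RefSeq gene table of assembly TAIR10.1, in which 32835 of the 33602 identifiers were found. The first digit of an identifier gives the chromosome.

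Replicate spread was tested per gene with edgeR's goodness-of-fit test on an intercept-only model (chi-square of the deviance, 2 degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. One version set the dispersion to 0 and asked whether a gene varied beyond counting error. The other used edgeR's trended dispersion and asked whether a gene varied beyond genes of its own level. On counts simulated from these 3 libraries for 18915 genes, with 1 library changed in 200 of them, the second test recovered 5 of 50 genes changed 1.5-fold, 37 of 50 changed 2-fold, 49 of 50 changed 4-fold and 50 of 50 changed 8-fold. It called 2 of 18715 unchanged genes. Each simulated gene was drawn independently at exactly the trended dispersion, and low counts were not made mostly even. Few calls of unchanged genes were thus built in, and these rates need not hold for the real counts.

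Before the data were examined, 23 gene lists were fixed: H3K4 methyltransferases, COMPASS core subunits, H3K4 demethylases, Polycomb repressive complex 2, H3.1 and H3.3 histone genes, nuclear photosynthesis genes, reference genes, markers of root, shoot meristem, floral organs, pollen and seed, and genes of flowering time, the circadian clock, heat, cold, touch and wounding, pathogen defence, hypoxia, iron deficiency, phosphate starvation and flavonoid synthesis. A member was kept where its list name was among the symbol and synonyms that the gene table gives its identifier, or where the table gives no name other than the identifier or a clone name. Otherwise it was left out, which removed JMJ16 (PKDM7D in the table), SAND (MON1) and HSP70-4 (HSP70). How symbols were matched (clone names, punctuation and prefixes ignored) was settled after counts and first list results had been seen, which restored EF1A to the reference genes, PSAD1 to photosynthesis and HSP22.0 to heat shock. The median log2(CPM + 1) of each list was compared with 10000 random lists of the same size from the 33323 nuclear genes. For members with a mean of at least 1 CPM (lists with at least 3 of them), the rank of the deviance and the log2 CPM of 1 library minus the mean of the other two (prior count 2) were compared with 10000 random lists matched on 20 bins of mean CPM. These tests are two-sided, 0.0002 is the smallest p they can give, and p was adjusted over the 23 lists, the 19 lists of the spread test or the 57 list and library pairs. Random lists treat genes as independent, and the correlation between genes was not estimated here.

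Genes named in the text were fixed by rule before the data were examined: all members of the lists of H3K4 methyltransferases, COMPASS core subunits and H3K4 demethylases, the 10 protein-coding genes with the highest level, the 2 highest and 2 lowest members of each other list, and the 10 genes with the smallest adjusted p beyond the trend among those with a mean of at least 5 CPM. Alternatives were DESeq2 1.42.0 size factors, other CPM minimums (0.5, 5 or none), a pseudocount of 0.1, random lists from expressed genes only, a common dispersion and leaving out each replicate in turn. Alternatives chosen after seeing the data were halved counts, removal of the 4 rRNA genes, protein-coding genes only, lists with the removed members kept, and list levels with members and random lists both limited to expressed genes. Values are given as mean ± SD over the 3 libraries.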

Results

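The transcriptome of wild-type Col-0 seedlings was measured by RNA-seq in 3 replicate samples, with 30946664, 18493022 and 20764970 counts assigned to genes. The study set out to relate the transcription level of each gene to its H3K4 methylation, in part by sorting genes into transcription levels. The chromatin libraries of the series were not analysed here. The data therefore answer which genes fall into which transcription level, how firmly 3 replicates place them there, and at what level the enzymes that write and erase H3K4 methylation were transcribed. With a single RNA group there was no contrast between conditions.

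Of the 33602 genes in the table, 18915 were expressed at a mean of at least 1 CPM, and 18461 of those are listed as protein-coding. No count was seen in any library for 9986 genes, of which 4325 are protein-coding and 4166 are listed as pseudogenes or transcribed pseudogenes. A further 4701 genes had a mean above 0 and under 1 CPM. The 1 to under 10 CPM class held 6231 genes, the 10 to under 100 CPM class 10701 genes, and the class of 100 CPM and over 1983 genes. That last class is 5.90% of the genes and took 59.1% of all CPM, and the 10 genes with the highest CPM, of which 1 is an rRNA gene, took 6.45%.

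The class of a gene was stable between libraries at high levels and unstable at low ones. Of genes with a mean of 10 to under 100 CPM, 94.8% lay in that class in every library, and 94.4% of genes at 100 CPM and over did so. The share was 85.2% at 1 to under 10 CPM and 42.4% above 0 and under 1 CPM, where a library without a count also counts as another class. Over the 23616 genes with a count in any library, 19314 (81.8%) kept 1 class. The median coefficient of variation over the 3 libraries was 14.7%, 6.07% and 3.61% for genes of 1 to under 10, 10 to under 100, and 100 CPM and over. Across all genes, which are not independent replicates, Pearson's r of log2(CPM + 1) between libraries was 0.997 to 0.998 and Spearman's rho was 0.988 for each pair. No pair was a repeat deposit of 1 library. The chi-square of a gene's counts between 2 libraries averaged 3.96 to 5.46, and 1.98 to 2.73 on halved counts, where sampling noise alone gives about 1.

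Photosynthesis genes were among the most abundant protein-coding transcripts. RBCS1A (AT1G67090), a small subunit of Rubisco, stood at 10326 ± 475 CPM (SD, n = 3), the highest protein-coding gene, followed by the light-harvesting gene LHCB1.3 (AT1G29930, CAB1 in the gene table) at 7065 ± 406 CPM and by RBCS3B (AT5G38410) at 5030 ± 184 CPM. RCA (AT2G39730), the Rubisco activase, reached 4510 ± 125 CPM and PSBO1 (AT5G66570), of the oxygen-evolving complex of photosystem II, 3220 ± 153 CPM. The other five of the 10 highest protein-coding genes were THI1 (AT5G54770, thiamine synthesis) at 4431 ± 172 CPM, PSBR (AT1G79040, photosystem II) at 3954 ± 231 CPM, the carbonic anhydrase CA1 (AT3G01500) at 3849 ± 116 CPM, GLDP1 (AT4G33010, glycine decarboxylase of photorespiration) at 3690 ± 133 CPM and AT3G60750 at 3097 ± 29.4 CPM. All 22 members of the nuclear photosynthesis list were expressed, down to LHCB2.1 at 68.4 ± 2.15 CPM and LHCB2.2 at 51.3 ± 6.04 CPM. Their median was 1296 CPM, above every one of 10000 random lists (adjusted p = 0.0015). The Rubisco, LHCB1 and LHCB2 copies are close relatives, so the split of reads between them is uncertain. How reads that match several copies were handled is not given, so LHCB2.1 and LHCB2.2 may be lowest through lost reads.

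Of the 23 fixed lists, 5 stood above random lists of nuclear genes and none below. Besides photosynthesis these were the reference genes, the touch and wounding genes, the H3.3 histone genes and the cold response genes. The 8 reference genes had a median of 410 CPM (adjusted p = 0.0015) and were led by UBQ10 (AT4G05320) at 1558 ± 12.5 CPM and EF1A (AT5G60390) at 1517 ± 19.6 CPM, with TIP41 at 27.6 ± 1.73 CPM and UBC21 at 21.6 ± 1.28 CPM the lowest. The 13 touch and wounding genes were all expressed, with a median of 78.4 CPM (adjusted p = 0.0015). LOX2 (AT3G45140), a lipoxygenase of jasmonate synthesis, reached 1319 ± 52.4 CPM and the storage protein gene VSP2 (AT5G24770) 212 ± 5.32 CPM. JAZ10 at 5.52 ± 0.744 CPM and RRTF1 at 3.38 ± 0.887 CPM were the lowest. The 3 H3.3 genes stood at 407 ± 16.8 CPM (AT4G40040), 223 ± 8.42 CPM (AT4G40030) and 147 ± 7.65 CPM (AT5G10980), with an adjusted p of 0.008. The cold response list had a median of 48.1 CPM (adjusted p = 0.041, and 0.16 with members and random lists both limited to expressed genes). COR47 (AT1G20440) stood at 363 ± 20.9 CPM and KIN2 (AT5G15970) at 265 ± 30.2 CPM, whereas the transcription factor genes CBF2 and CBF3 stood at 1.60 ± 0.259 and 0.596 ± 0.174 CPM.

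**Figure D1:**
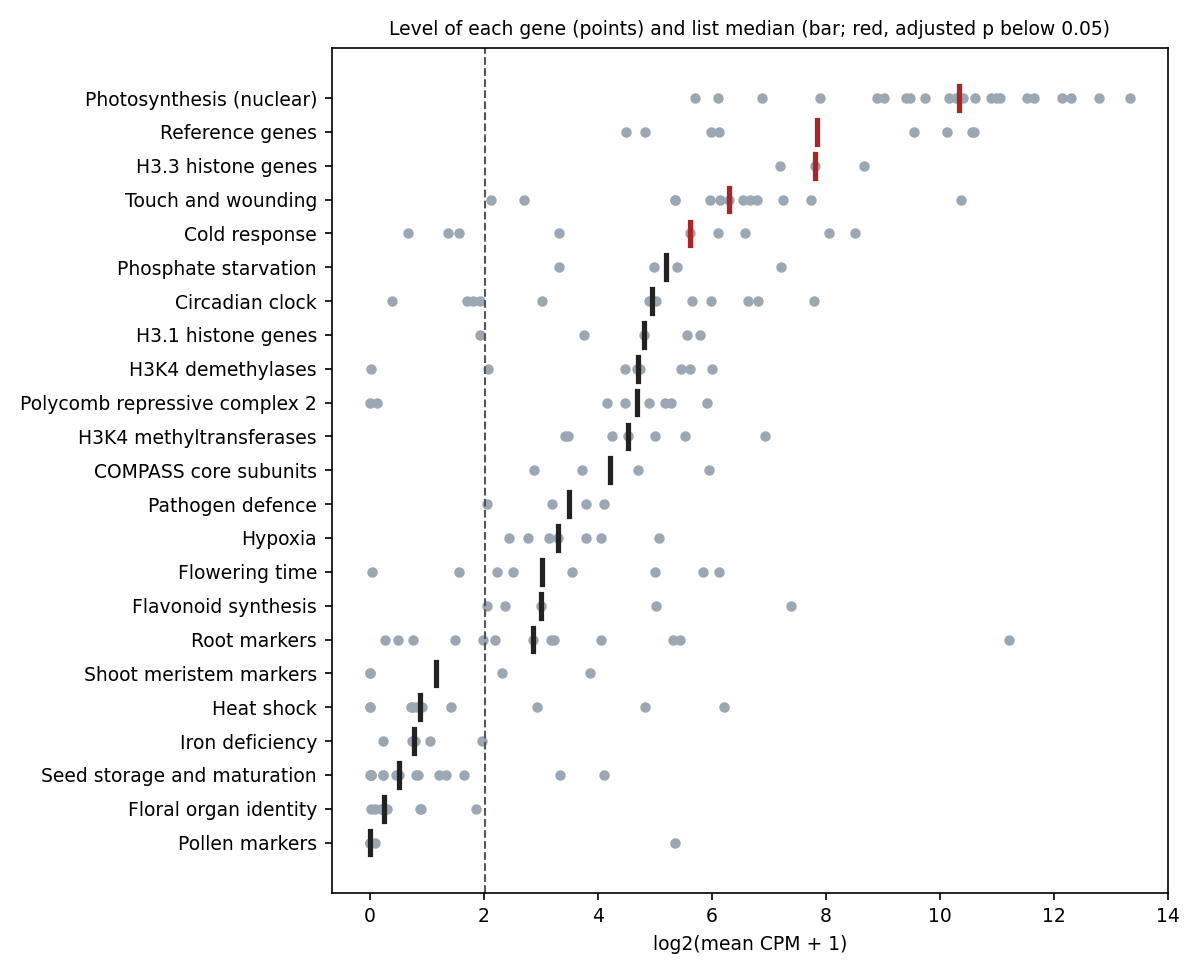
Level of each member (points) and median (bars) of the 23 gene lists on a log2(mean CPM + 1) axis, over 3 libraries, with the typical median of random lists of nuclear genes as a dashed line. The 5 red medians, from 48.1 CPM (cold response) to 1296 CPM (photosynthesis), lay above random lists at an adjusted p below 0.05.

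The floral, pollen, seed and shoot meristem lists had medians under the typical median of random nuclear lists. None of these lists passed the threshold against random lists (adjusted p from 0.50 to 0.66), and many nuclear genes have no count. Only 1 of 8 floral organ identity genes was expressed, SEP3 (AT1G24260) at 2.65 ± 0.436 CPM, with SEP1 at 0.863 ± 0.156 CPM. AG (0, 2 and 2 counts in replicates 1 to 3) and AP3 (2, 0 and 0 counts) were the lowest. Of the 5 pollen genes TUA1 (AT1G64740) stood at 40.2 ± 2.66 CPM, ANX1 had 4 counts in replicate 3 alone, and ANX2 and AT5G45880 had none. In the seed list 5 of 15 genes were expressed, led by the storage protein genes CRA1 (AT5G44120) at 16.2 ± 1.13 CPM and CRC (AT4G28520) at 9.07 ± 2.63 CPM. The seed regulator LEC2 had 2, 0 and 0 counts and LEC1 none. Of the 4 shoot meristem genes KNAT1 stood at 13.6 ± 0.761 CPM and STM at 3.98 ± 0.0317 CPM, and WUS and CLV3 had no count, which allows up to 0.162 CPM in the shallowest library. With members and random lists both limited to expressed genes, an alternative chosen after seeing the data, the 5 expressed seed genes lay below random lists (median 2.15 CPM, adjusted p = 0.026), and the floral, pollen and shoot meristem lists had under 3 members left and were not tested. Of 13 root markers 10 were expressed (median 6.29 CPM, at the 68.3rd percentile of random nuclear lists, adjusted p = 0.66). PYK10 (AT3G09260), a beta-glucosidase of ER bodies, stood at 2385 ± 9.71 CPM and the phosphate transporter gene PHT1;1 (AT5G43350) at 42.6 ± 0.860 CPM. WOX5 (18, 12 and 0 counts) and the nitrate transporter gene NRT2.1 (0.212 ± 0.0815 CPM) lay under 1 CPM.

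Stress and nutrient lists other than cold and wounding did not pass the threshold against random nuclear lists (adjusted p from 0.23 to 0.72). These lists are small, so a difference is not excluded, and phosphate starvation lay at the 95.5th percentile. The heat shock list split within itself, with 4 of 10 genes expressed. The chaperone genes HSP90.1 (AT5G52640) and HSP101 (AT1G74310) stood at 73.7 ± 3.13 and 27.5 ± 2.57 CPM, and the small heat shock protein genes HSP21 and HSP22.0 had no count. HSP70-4 (AT3G12580), left out of the list and outside the naming rule, stood at 126 ± 2.84 CPM. In the iron deficiency list BHLH101 stood at 2.94 ± 0.988 CPM, FRO2 at 1.09 ± 0.173 CPM, BHLH39 at 0.667 ± 0.485 CPM and BHLH38 at 0.173 ± 0.163 CPM. The 4 phosphate starvation genes were all expressed, with SPX1 at 148 ± 10.6 CPM, PHT1;4 at 40.9 ± 1.64 CPM, MGD3 at 30.9 ± 0.678 CPM and SPX3 at 8.97 ± 0.787 CPM. All 7 hypoxia genes were expressed, between ADH1 at 32.6 ± 2.53 CPM and SUS4 at 15.7 ± 1.37 CPM at the top and PCO1 at 5.83 ± 0.523 CPM and PCO2 at 4.42 ± 0.378 CPM at the bottom. The defence genes PR2, PDF1.2, PR5 and PR1 stood at 16.3 ± 0.254, 12.9 ± 0.696, 8.13 ± 0.871 and 3.19 ± 0.340 CPM. In flavonoid synthesis CHS stood at 167 ± 5.75 CPM, F3H at 31.4 ± 0.569 CPM, LDOX at 4.20 ± 1.31 CPM and the regulator PAP1 at 3.19 ± 0.549 CPM.

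Of the 12 circadian clock genes 11 were expressed, with a median of 30.2 CPM (adjusted p = 0.070). TOC1 (AT5G61380) and ELF3 (AT2G25930), which act around dusk, were the highest at 222 ± 5.42 and 111 ± 1.37 CPM. LHY (AT1G01060) and PRR9 (AT2G46790), which peak in the morning, were the lowest at 2.26 ± 0.310 and 0.312 ± 0.0172 CPM. The time of day at harvest is not given in the sources used here. Of 8 flowering time genes 7 were expressed (median 7.69 CPM, adjusted p = 0.66). The repressor gene SVP (AT2G22540) stood at 68.9 ± 2.54 CPM and SOC1 (AT2G45660) at 56.4 ± 2.77 CPM, against 1.95 ± 0.241 CPM for FT, which encodes the mobile flowering signal, and 0, 0 and 2 counts for its relative TSF.

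All 7 H3K4 methyltransferase genes were expressed, and ATXR3 (AT4G15180), known for trimethylation of H3K4, was the highest at 121 ± 12.0 CPM. Its counts were 47.0 ± 1.76% of those of the 7 genes. ATX2 (AT1G05830) followed at 45.3 ± 2.47 CPM, ATXR7 (AT5G42400) at 31.2 ± 0.739 CPM, ATX5 (AT5G53430) at 22.0 ± 1.52 CPM and ATX4 (AT4G27910) at 18.1 ± 1.81 CPM. ATX3 (AT3G61740) at 10.1 ± 1.79 CPM and ATX1 (AT2G31650) at 9.70 ± 0.114 CPM were the lowest, and their means differed by less than the SD of ATX3. ATXR3 exceeded ATX2 in 3 of 3 libraries, a comparison in which an exact sign-flip test cannot give a two-sided p under 0.25. These levels are not corrected for transcript length. The list median was 22.0 CPM, at the 91.9th percentile of random nuclear lists (adjusted p = 0.34 over the 23 lists).

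The subunits that these enzymes share in COMPASS-like complexes were expressed as well, 4 of 4. S2LB (AT5G66240) stood at 60.6 ± 4.55 CPM, RBL (AT3G21060) at 25.1 ± 0.267 CPM, ASH2R (AT1G51450) at 12.2 ± 1.32 CPM and WDR5A (AT3G49660) at 6.35 ± 0.490 CPM (list median 18.7 CPM, adjusted p = 0.50).

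Of the 8 H3K4 demethylase genes kept in the list 7 were expressed. JMJ14 (AT4G20400), a JmjC demethylase, stood at 63.2 ± 1.74 CPM, LDL3 (AT4G16310) at 48.2 ± 5.42 CPM and JMJ18 (AT1G30810) at 42.9 ± 4.86 CPM. JMJ17 (AT1G63490) at 25.6 ± 2.71 CPM, FLD (AT3G10390) at 24.8 ± 2.95 CPM and LDL1 (AT1G62830) at 21.2 ± 0.563 CPM followed, and JMJ17 and FLD differed by less than the SD of either. LDL2 (AT3G13682) stood at 3.21 ± 0.674 CPM, and JMJ15 (AT2G34880) had 2, 0 and 0 counts, under the floor of 3 counts in each library. AT1G08620, entered as JMJ16 and carried as PKDM7D in the gene table, was left out of the list and stood at 50.2 ± 3.62 CPM. Summed over each list, methyltransferases reached 258 ± 16.1 CPM and demethylases 229 ± 13.4 CPM. With AT1G08620 counted, an alternative chosen after seeing the data, the demethylase sum was 279 ± 16.98 CPM and the order of the lists turned, so no order is drawn from these sums. The demethylase list median was 25.2 CPM, at the 96.0th percentile of random nuclear lists (adjusted p = 0.23).

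**Figure D2:**
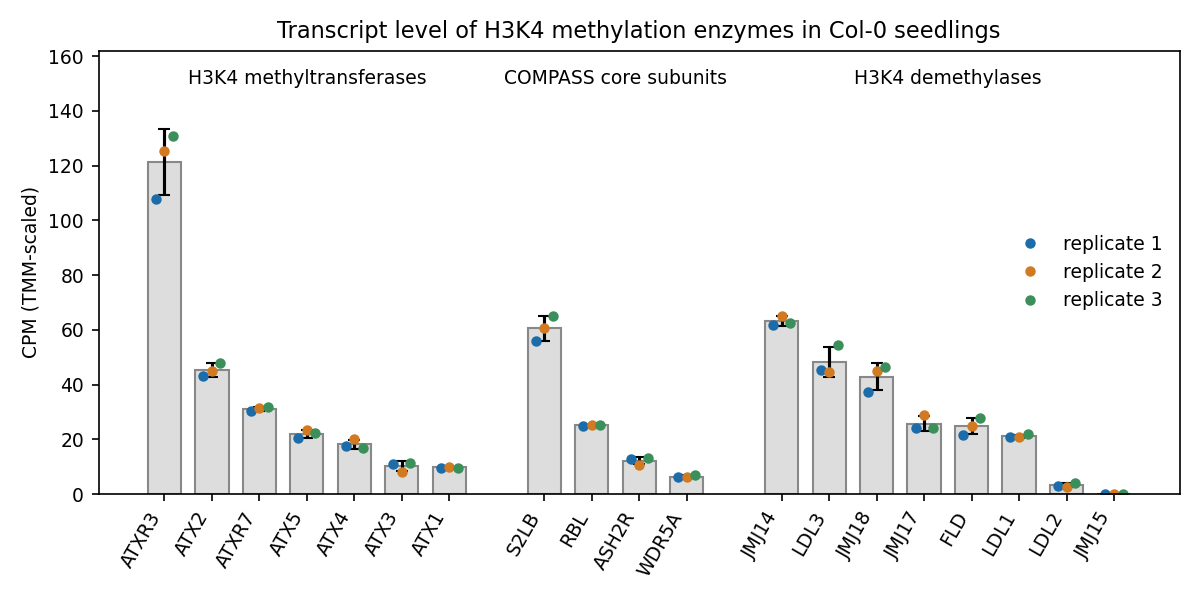
CPM of the H3K4 methyltransferase, COMPASS core subunit and H3K4 demethylase genes, with points for the 3 replicates, grey bars for the mean and error bars for the SD. ATXR3, at 121 ± 12.0 CPM, stood above the other genes of the 3 lists in every replicate, and JMJ15 was close to 0.

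In Polycomb repressive complex 2, which places the repressive H3K27 mark, SWN stood at 59.8 ± 2.002 CPM and MSI1 at 37.9 ± 1.73 CPM, while MEA had 2 counts in each library and FIS2 had none (6 of 8 expressed, list median 25.1 CPM, adjusted p = 0.23). The 5 H3.1 genes, whose products enter chromatin at replication, had a median of 27.1 CPM (adjusted p = 0.34). AT5G65360 at 54.5 ± 4.53 CPM and AT1G09200 at 46.1 ± 5.04 CPM were the highest of them, and AT5G10390 at 12.6 ± 0.761 CPM and AT3G27360 at 2.83 ± 0.618 CPM the lowest. Histone gene copies are similar in sequence, so the split between them is uncertain.

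The replicates differed most in rRNA and a few other transcripts, mainly in replicate 3. The 4 rRNA genes took 1.201%, 1.39% and 2.97% of the counts of replicates 1, 2 and 3 (95% Wilson intervals 1.198 to 1.205%, 1.38 to 1.39% and 2.96 to 2.98%), and AT3G41768 alone held 99.6%, 99.7% and 99.1% of those rRNA counts. Of 18915 genes tested, 28 varied beyond genes of their own level (edgeR goodness-of-fit with the trended dispersion, adjusted p below 0.05). In that test 872 had an unadjusted p under 0.05, a share below the 0.05 that arises with no excess variation. The trend was fitted to these same genes and libraries, so a share near 0.05 is largely built in and is no independent check. In 15 of the 28 replicate 3 was the library farthest from the other two and higher, and in 5 it was the farthest and lower. Without replicate 3 only 6 genes passed, 4 of them among the 28. Without replicate 1, 19 genes passed, 16 of them among the 28.

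Among the 10 named genes of that test, 8 were highest in replicate 3. The rRNA gene AT3G41768 stood at 11965, 13654 and 29757 CPM in replicates 1 to 3, the rRNA gene AT2G01010 at 33.3, 27.0 and 187 CPM, and the rRNA gene AT3G41979 at 15.6, 16.1 and 63.8 CPM. AT2G01021, listed as protein-coding and next to the rRNA gene AT2G01020, stood at 8.31, 6.84 and 59.6 CPM. The U1 small nuclear RNA gene AT1G08115 stood at 1.65, 0.535 and 15.7 CPM, and the noncoding RNA gene AT1G15405 at 4.14, 0.962 and 55.5 CPM. The protein-coding genes AT5G36790 (5.14, 7.002 and 101 CPM) and AT2G31141 (1.03, 1.07 and 15.3 CPM) were also highest in replicate 3. The remaining pair were lowest in replicate 1. LpxC3 (AT1G25054), an enzyme gene of lipid A synthesis with several copies, stood at 16.4, 91.6 and 84.8 CPM, and SAE1B (AT5G50580), a SUMO-activating enzyme gene whose symbol the gene table also gives to AT5G50680, at 0.743, 9.14 and 5.55 CPM. The adjusted p of the 10 genes ran from 3.62e-193 to 6.98e-15. Leaving out replicate 3 ended the call for 7 of them, and leaving out replicate 1 ended it for LpxC3 and SAE1B. AT1G15405 kept an adjusted p of 0.019 without replicate 3.

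**Figure D3:**
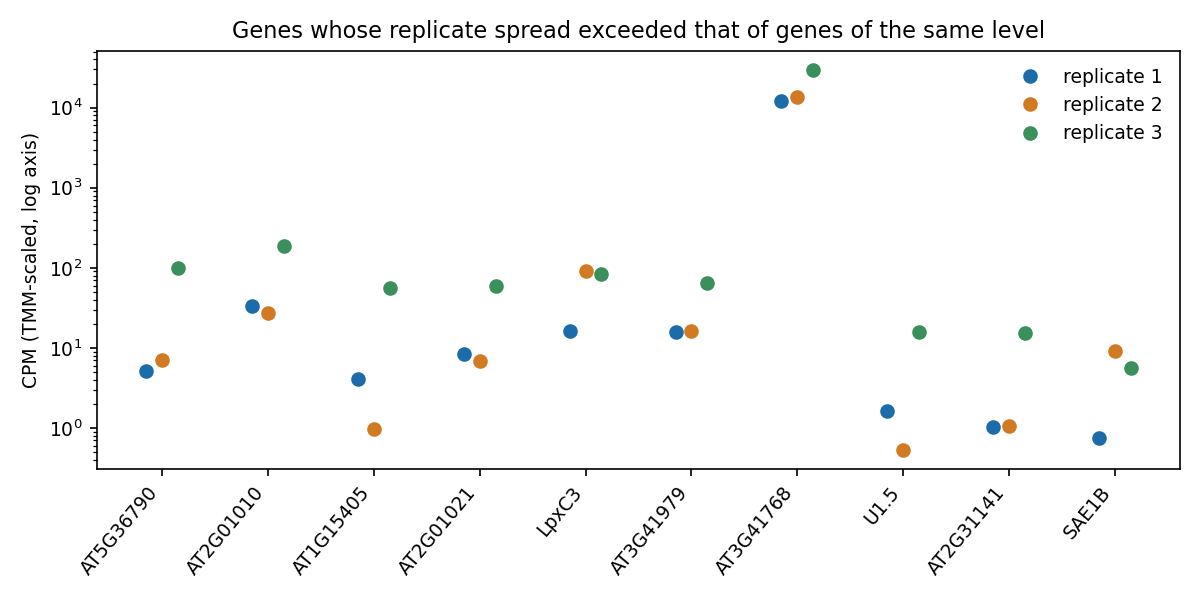
CPM on a log axis of the 10 named genes whose spread exceeded that of genes of the same level, with 1 point per replicate. In 8 genes replicate 3 was the highest, such as AT5G36790 at 101 CPM against 5.14 and 7.002 CPM, and LpxC3 and SAE1B were lowest in replicate 1.

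The photosynthesis genes differed between replicates together, by a small amount. Replicate 1 was higher than the mean of the other libraries in 22 of 22 genes, with a median log2 difference of 0.11 (adjusted p = 0.0057), and replicate 2 was lower in 19 of 22, with a median of -0.10 (adjusted p = 0.0057). In replicate 3, where the rRNA share was highest, the median was -0.03 (adjusted p = 0.50). Their deviance rank averaged 69.4 on a scale to 100, against 44.4 in matched random lists (adjusted p = 0.0038), the only one of 19 lists past the threshold. In the rank and shift tests level was matched by bin only, not within the highest bin. Members such as RBCS1A lay at the 99.99th percentile of expressed genes, so a part of level in these results stays open. These tests treat genes as independent, so p is too small where members of a list vary together. Without replicate 1 or replicate 2 that call was lost (mean rank 54.7, adjusted p = 0.74, and 58.2, adjusted p = 0.44). In replicate 1 the reference genes were also higher in 8 of 8 (median 0.055, adjusted p = 0.62 against matched random lists). The H3K4 demethylases were lower there in 7 of 7 (median -0.12, adjusted p = 0.50). A shift of all members to 1 side was thus not particular to the photosynthesis list. No list but photosynthesis passed the threshold in any library under these settings. The H3K4 demethylases came next, with a median log2 difference of 0.18 in replicate 3 and 5 of 7 genes higher (adjusted p = 0.068). That call hangs on the setting, since the adjusted p was 0.049 with DESeq2 size factors, 0.034 to 0.046 in 3 alternatives chosen after seeing the data, and 0.28 or 0.59 with a minimum of 5 CPM or none.

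Measured against counting error alone, 6197 of 18915 genes varied between the replicates (edgeR goodness-of-fit with dispersion 0, adjusted p below 0.05). With replicate 1, 2 or 3 left out the number was 2964, 3862 or 3172. On halved counts, a setting chosen after the even counts were seen, 1207 of 18929 genes did. Of the 7 methyltransferase genes 2 passed (2 adjusted over the list alone, 1 on halved counts), and of the 7 demethylase genes tested 4 did (4 adjusted over the list alone, 2 on halved counts). In the photosynthesis list 21 of 22 passed, and again 21 adjusted over the list alone and 21 on halved counts. A test against counting error detects smaller differences at higher counts. The list medians were 1296 CPM for photosynthesis, 22.0 CPM for methyltransferases and 25.2 CPM for demethylases, so these shares do not rank the lists by variation. No member of any fixed list varied beyond the trend over all genes. In that edgeR test 9 of 146 entries had an unadjusted p under 0.05, where a share of 0.05 arises with no excess variation. That share is relative to a trend fitted to all expressed genes of the same libraries. Adjusted over the list alone, 1 cold response gene and 1 seed gene did.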

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

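The number of expressed genes ran from 15319 to 19985 over its alternatives, and, for the expression classes, the share of genes that kept 1 class from 81.8% to 87.8%. For replicate agreement, the lowest r between libraries ran from 0.992 to 0.997. The count of genes beyond counting error fell from 6197 to between 2964 and 3862 with 1 replicate left out, where fewer libraries are tested, and to 1207 on halved counts. In a simulation of doubled Poisson counts for 18915 genes, 976 passed with no variation between libraries, and 0 passed with plain Poisson counts. Genes beyond the trend numbered 28, and 6 to 29 with 1 replicate left out (6 without replicate 3), 161 with a common dispersion, which ignores that low genes vary more, and 25 on halved counts or without the 4 rRNA genes. The number of lists apart from random lists was 5, and 10 with random lists of expressed genes only. That filter left unexpressed members in the lists and so fixed the outcome for the 5 lists with a median under 1 CPM, and nothing is drawn from the 10. With the filter on members too, chosen after seeing the data, 5 of 19 lists passed: the seed list lay below random lists (adjusted p = 0.026) and the cold response list lost its call (adjusted p = 0.16), as it did without the 4 rRNA genes (adjusted p = 0.059). The floral, pollen, shoot meristem and iron deficiency lists had under 3 expressed members and got no value there. The photosynthesis list was the only list past the spread test, and the number of such lists was 0 to 1 with 1 replicate left out. The difference of the H3K4 demethylases in replicate 3 passed the threshold with DESeq2 size factors (adjusted p = 0.049), on halved counts (0.034), without rRNA genes (0.042) and with JMJ16 kept (0.046), and missed it with a minimum of 5 CPM (0.28) or none (0.59). Of the 28 genes beyond the trend, 4 stayed past the threshold without replicate 3 (21 did not and 3 were not tested), 16 without replicate 1 (11 did not and 1 was not tested) and 25 without replicate 2. Among the 10 named ones, 7 calls were lost without replicate 3 and 2 without replicate 1. In 8 cases the recomputed level of a named or listed gene moved by more than 1 SD, and the demethylase sum moved from 229 to 279 CPM with JMJ16 kept. The direction of a list changed sides in 42 cases, 12 for level, 13 for replicate spread and 17 for shift, with 0 of these past the threshold in the alternative; the cause was not tested except where the random lists themselves changed. For list expression level this came from random lists of expressed genes, with a median log2(CPM + 1) of 4.22 (COMPASS core subunits), 3.001 (flavonoid synthesis), 3.03 (flowering time), 3.302 (hypoxia), 3.49 (pathogen defence) and 2.87 (root markers), or 3.54 for flowering time and 3.21 for root markers with the filter on members too. For list replicate spread, the mean rank of the circadian clock was 44.4 with no filter and 47.7 with a minimum of 5 CPM, and that of flavonoid synthesis 46.8 with that minimum. With 1 replicate left out the mean rank ran from 47.2 to 57.7 for the circadian clock, 44.0 to 61.6 for the H3.1 genes, 45.2 to 60.1 for the H3K4 methyltransferases, 39.0 to 49.6 for phosphate starvation, 39.9 to 57.7 for Polycomb repressive complex 2, 43.9 to 58.1 for seed genes and 40.7 to 55.5 for touch and wounding. For list shift per library, the median log2 difference with no filter was 0.0321 for the circadian clock and 0.0103 for seed genes in replicate 1, and -0.0058 for the H3K4 demethylases in replicate 2. With a minimum of 5 CPM it was 0.0015 for the circadian clock and -0.0119 for touch and wounding in replicate 1. In replicate 2 it was 0.0181 for flowering time, -0.059 for hypoxia, -0.0113 for reference genes, -0.0487 for root markers and 0.0126 for touch and wounding. In replicate 3 it was 0.0226 for cold response, -0.022 for flowering time, 0.0134 for the H3.1 genes and 0.0024 for touch and wounding. For the circadian clock in replicate 1 it was 0.0039 on halved counts and 0.006 without rRNA genes, and for heat shock in replicate 2 it was -0.0194 with HSP70-4 kept. CPM over nuclear genes only changed nothing, since organelle genes were listed at 0, and the alternatives that compare TPM with CPM or use gene features were not run. Depth limits statements on genes above 0 and under 1 CPM, of which 42.4% kept 1 class.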

Other observations

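All tests of explanations in this part were chosen after the patterns were seen. Beyond the protein-coding genes, 93 of 3911 genes listed as pseudogenes and 79 of 926 listed as transcribed pseudogenes reached 1 CPM. Of 224 long noncoding RNA genes 133 reached 1 CPM, as did 14 of 178 microRNA genes and none of 623 tRNA genes. Among the 28 genes beyond the trend, some protein-coding genes outside the naming rule were picked here after their values were seen. JMT (AT1G19640), a jasmonate methyltransferase gene, stood at 1.33, 2.35 and 0.146 CPM in replicates 1 to 3. AT3G08520, AT3G56020 and AT1G56045 were highest in replicate 1 and lowest in replicate 3 (69.2, 60.8 and 42.9 CPM, 33.0, 24.3 and 18.9 CPM, and 74.7, 60.3 and 49.5 CPM). BIG (AT3G02260), an auxin transport gene, was lowest in replicate 1 and highest in replicate 3, at 252, 290 and 346 CPM. In the edgeR test the calls of AT3G08520, AT3G56020, AT1G56045 and BIG were lost without replicate 1 (adjusted p from 0.21 to 0.999). The same calls were lost without replicate 3 (adjusted p from 0.61 to 0.98). Whether transcript length or sequence shared with other genes plays a part was not tested.

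Low counts were mostly even. In replicate 1, 813 genes had 2 counts and 78 had 1, and 469 had 4 counts and 61 had 3. Doubling of a whole column after counting is argued against, since at most 51.1% of counts of 1000 and over were even. Separate counting of both mates of a read pair stays open: the smallest ratio in any library, of genes at 2 counts to genes at 1 or of genes at 4 to genes at 3, was 7.69, but that restates the share of even counts and decides nothing, and the sources used here do not state how pairs were counted. No biological explanation was tested.

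rRNA was higher in replicate 3. AT3G41768 made up 98.7% of the difference in the rRNA share, but the other 3 rRNA genes were higher too, with a smallest log2 difference of 2.004. The 14 expressed snoRNA genes did not rise as a set, with a median log2 difference of -0.22 (quartiles -0.59 and 0.19) and 9 of 14 lower in replicate 3. The smallest difference of an rRNA gene was 1.22. These values argue against a rise of all RNA without a poly(A) tail only if the snoRNA reads came from such RNA. That was not tested, and all snoRNA genes together held 0.0040%, 0.0039% and 0.0035% of the counts of replicates 1, 2 and 3. A joint carry-over of rRNA and snRNA stays open: the median of the 3 expressed snRNA genes was 2.51, but only 1 of them reached a mean of 1 CPM without replicate 3 and 2 are among the 28 genes beyond the trend, so that value decides nothing. The design gives no group for replicate 3, so no biological explanation was tested.

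Several genes beyond the trend belong to sets of copies, among them LpxC1, LpxC3, SAE1B and SPL13A. Reads moved between the same-named copies could produce the differences of LpxC3, SAE1B and SPL13A only if the sum stayed level. The summed CPM differed by at least 5.08 times between libraries in each set. For LpxC1 (2.39, 2.14 and 0.195 CPM) the sum decides nothing, since LpxC3 made up most of it. LpxC3 held 508, 1713 and 1742 of 587, 1802 and 1748 counts. Sets were formed by shared symbol only, so genes without a symbol, such as AT5G36790, AT3G08520, AT3G56020 and AT1G56045, were not covered. The sums were 18.97, 96.3 and 85.1 CPM for LpxC1 to LpxC5, 0.970, 9.25 and 5.94 CPM for the SAE1B pair, and 2.42, 1.23 and 0.341 CPM for SPL13A and SPL13B. A loss of reads that match several copies, differing between libraries, stays open, since such reads were not analysed here. A difference between the plants sampled stays open as well and was not tested.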
